A study of Sus scrofa with 6 samples.

How the data were processed

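RNA from 6 pig samples was measured on the Affymetrix Porcine Genome Array, 1 array per sample. Each of the 5 embryo samples pooled between 23 and 26 nuclear transfer embryos collected 28 h after transfer, and 1 sample held the cultured donor cells. Per the labels' protocols, RNA was extracted with the Picopure kit, and 50 ng of total RNA per sample was labelled with biotin by a two-cycle method in which the reverse transcription step was modified. Per the labels, the deposited values are probe set intensities on a linear scale, and MAS5, the array maker's summary method, is named in the submitters' processing notes. Its version, the scaling target and detection calls are not given in the sources used here. The values themselves show a common scaling, since the mean of each array after leaving out the lowest and highest 2% of probe sets lay between 500.1 and 500.2.

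The table held 24123 probe sets, of which 124 were control probe sets of the array and were left out of all tests. Of the other 23999, the platform annotation used here gave a single gene symbol to 10069, several symbols to 198 and none to 13732. Probe sets with several symbols or none were tested but not named, and the annotation can be old. No column of values was left without a sample. The gene for DJ-1 is PARK7.

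Samples were grouped by their labels into anti-DJ1 embryos (n = 2), IgG embryos (n = 2), non-injected embryos (n = 1) and donor cells (n = 1). The study ran 2 trials. Trial 1 held 1 array of each of the 4 groups, and trial 2 held a further anti-DJ1 array and a further IgG array. The design text describes the second pair as biologically different samples, and names the IgG array of each trial as that trial's control, so the trial was kept as a block. The pairing was checked from the values: over 14399 probe sets, the deviations of the anti-DJ1 and IgG arrays of the same trial from their group means correlated at r = 0.588, across probe sets, which are not independent replicates. The non-injected and donor cell groups are single arrays. Tests against them assume that a single array varies like the replicated ones.

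Values were set to log2(signal + 4.57), where 4.57 is the 10th percentile of all signals, and were otherwise kept as deposited. Fold changes are on this scale, which understates the change of dim probe sets. Probe sets whose mean lay in the upper 60% were tested, which left 14399 with a mean signal above 39.6. Of these, 6850 had a single symbol and covered 5218 genes. The test was limma (lmFit and eBayes with a mean-variance trend, version 3.58.1, in R 4.3.3) on all 6 arrays with group and trial as terms, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This leaves 1 residual degree of freedom, to which the moderation added 10.7. Every adjusted p for a gene is from this test. Errors beside log2 changes are standard errors (SE) of the fit, and errors beside signals are SDs over arrays. The small number of arrays limits the precision. For anti-DJ1 against IgG embryos, the median 95% confidence interval of a probe set reached 1.42-fold to either side, from 2.00-fold among the dimmest 3600 tested probe sets to 1.21-fold among the brightest 3600. For the comparisons with the single non-injected array it reached 1.59-fold.

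A further count, with no test per gene, took the probe sets that changed at least 2-fold the same way in both trials and set it beside those that changed at least 2-fold in opposite directions. Donor-high and embryo-high transcripts were those at least 8-fold apart between the donor cell and the non-injected array, neither of which enters the comparison of anti-DJ1 with IgG embryos.

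The 20 gene lists were apoptosis regulators, oxidative stress response, DJ-1 partners and mitophagy, DNA damage response, heat shock and unfolded protein response, cell cycle and mitosis, maternal oocyte transcripts, embryonic genome activation and translation, pluripotency and early lineage, chromatin and DNA methylation, imprinted genes, fibroblast and extracellular matrix, smooth muscle and actin cytoskeleton, cumulus and granulosa cells, epithelial, endothelial and blood cells, ribosomal proteins, oxidative phosphorylation, proteasome and ubiquitin, glycolysis, and interferon and inflammatory response. Each gene was represented by the probe set with the highest mean, and a list needed at least 5 measured members. Lists were tested with limma's camera with a preset correlation of 0.01 between members and again with an estimated correlation, with adjustment over 21 lists, of which 1 is not reported here.

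Named genes followed a fixed rule. PARK7 was always named. Then came, for each comparison, up to 10 genes in each direction with the largest change among those past the threshold, with every array of the replicated group on the same side, and where fewer passed, genes at least 2-fold apart in both trials or on every array, as values. From each list came up to 4 members with the smallest unadjusted p. The mean of the higher group had to exceed a signal of 118. The groups, designs, lists, naming rule and all alternatives except those said to be added later were chosen before the data were examined.

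The 17 Tag control probe sets, which match no pig transcript, gave the background. Where all arrays of a group lay at or under the array's highest Tag signal, the fold is given as at least the brighter group's mean over a floor at that Tag signal. That mean averages the group's arrays of both trials with no term for the trial. It is therefore not a bound on the change in the fit. The control ratios used in the closing section count a signal as away from the background at 4 or more times the highest Tag signal, a factor chosen after the values were seen.

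The test was tried on simulated data built on these arrays, with 200 of 14399 probe sets changed in the comparison of anti-DJ1 with IgG embryos, over 40 simulations. It recovered 20.6% of 1.5-fold, 50.8% of 2-fold, 86.9% of 4-fold and 95.3% of 8-fold changes, and 16.3% of its calls were false, above the 5% intended. With only the upper 40% of probe sets (9600), it recovered 47.2% of 1.5-fold and 87.5% of 2-fold changes, and 6.10% of calls were false. Spreads were drawn from the prior of the fit being tried, so the simulations do not test that prior.

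The alternatives were quantile normalization, a common 75th percentile, a pseudocount at the 25th percentile or none, no filter or the upper 40% of probe sets, no block for the trial, no mean-variance trend, fewer groups in the fit or contrast, other fold limits, other rules for lists, and each replicated array left out in turn, in fits without the block. A filter at the Tag controls and a contrast without the non-injected array were chosen after seeing the data. An alternative counted as the opposite of the reported value when the sign changed and either value passed the threshold, and as moved when neither passed. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.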

Results

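Transcript levels were measured in pig embryos made by nuclear transfer (NT), in which the nucleus of a cultured donor cell is placed in an oocyte, and in the donor cells themselves. The donor cells were fibroblasts from an adult Meishan pig, and the oocytes came from a slaughterhouse. The series asks how DJ-1, a redox-sensitive protein encoded by PARK7, acts in the early development of such embryos. Embryos received an antibody against DJ-1 (2 arrays), control IgG (2 arrays) or no injection (1 array), and were collected 28 h after transfer, at about the 2-cell stage, in pools of 23 to 26. The donor cells gave 1 array. Trial 1 held 1 array of each kind, and trial 2 repeated the anti-DJ1 and IgG embryos.

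The 6 arrays shared a trimmed mean of about 500.1, and between 55.8% (non-injected embryos) and 71.0% (IgG embryos of trial 1) of the 23999 probe sets lay above the array's highest Tag control, which ranged from 21.4 to 47.0. The 10 pairs of embryo arrays correlated at r = 0.936 to 0.982 across probe sets, and the 5 pairs of an embryo array with the donor cell array at 0.355 to 0.421, where probe sets are not independent replicates. The arrays also differed in their controls. The 3′ over 5′ signal ratio of EF1A, which rises when labelled RNA is short, was 24.2, 23.9 and 30.0 on the anti-DJ1, IgG and non-injected arrays of trial 1, and 8.20 and 9.34 on the anti-DJ1 and IgG arrays of trial 2. It was 4.23 on the donor cell array.

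**Figure D1:**
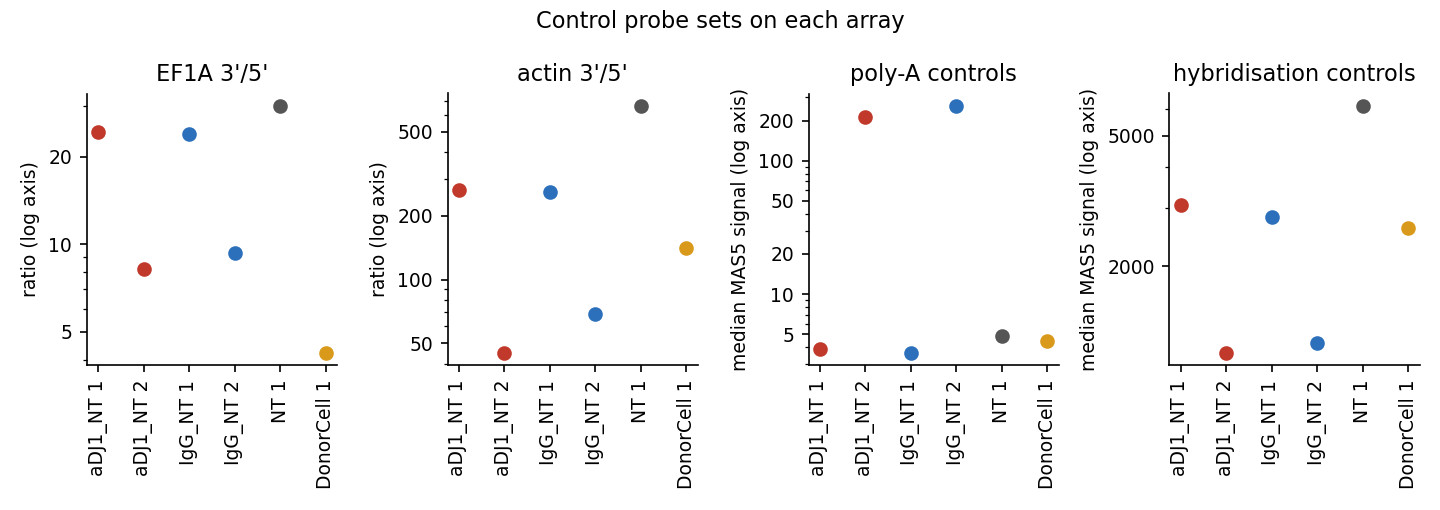
Control signals on each of the 6 arrays, on log axes: the 3′ over 5′ signal ratios of EF1A and actin, and the median MAS5 signals of the poly-A and hybridisation control probe sets. The EF1A ratio lies at 23.9 to 30.0 on the embryo arrays of trial 1, at 8.20 and 9.34 on those of trial 2 and at 4.23 on the donor cell array.

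The comparison of anti-DJ1 with IgG embryos addresses what blocking DJ-1 does to transcripts. PARK7 itself, on chromosome 6, had a signal of 825 ± 535 (SD, n = 2) in anti-DJ1 and 897 ± 529.7 (n = 2) in IgG embryos, a log2 change of -0.15 ± 0.14 (SE, limma, adjusted p = 0.944), with -0.22 in trial 1 and -0.08 in trial 2. Its confidence interval ran from -0.47 to 0.16. The antibody binds the protein, so this transcript is no check of the injection. No probe set of 14399 passed the threshold in limma, while 838 had an unadjusted p under 0.05, where 719.95 would by chance, and the lowest adjusted p was 0.0882. With only the upper 40% of probe sets tested, 43 of 9600 passed (33 higher, 10 lower), and 15 of them changed by over 0.5 on the log2 scale the same way in both trials. On simulated data that fit made 6.10% false calls against 16.3% for the fit reported, and recovered 87.5% against 50.8% of 2-fold changes. Each simulation drew its spreads from the prior of its own fit, and the upper 40% fit had prior degrees of freedom of 90.01. The simulation thus assumed near-equal spreads at a given signal, and does not show that the 43 calls are sound. Without the block for the trial, the PARK7 change ran from -0.86 without anti-DJ1 replicate 2 to 0.56 without anti-DJ1 replicate 1, with -0.79 without IgG replicate 1 and 0.49 without IgG replicate 2. Each of these fits leaves the trials unbalanced, and PARK7 was higher in trial 2 than in trial 1 by 1.35.

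The probe set with that lowest adjusted p, Ssc.7628.1.A1_at, has no gene name in the annotation used here and was chosen after its values were seen. Its signals were 9951 in trial 1 and 2608 in trial 2 in anti-DJ1 embryos against 5751 and 1374 in IgG embryos, a log2 change of 0.86 ± 0.12 (limma, adjusted p = 0.0882), with 0.79 and 0.92 in the 2 trials. It passed under quantile normalization (adjusted p = 0.0493), a common 75th percentile (0.0217) and a pseudocount at the 25th percentile (0.00544). It did not pass with no pseudocount, no filter on low values, no block for the trial or no mean-variance trend. Its signal was 1482 in non-injected embryos and 16552 in donor cells.

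In the DNA damage response list, CHEK1, the checkpoint kinase that holds the cell cycle when replication stalls, had a signal of 8662 ± 901 in anti-DJ1 and 6117 ± 1635 in IgG embryos (n = 2 each), a log2 change of 0.52 ± 0.12, with 0.35 and 0.69 in the trials. Its adjusted p was 0.753 over all probe sets in limma and 0.0119 adjusted over the list alone, and with only the upper 40% of probe sets it was 0.0112 over all. The signal of this probe set on the single non-injected array was 8780. Against that array, anti-DJ1 embryos stood at a log2 change of 0.17 and IgG embryos at -0.36. A second, dimmer CHEK1 probe set changed by -0.14. CHEK1 was the 1 gene to pass when adjusted over the list alone across the 20 lists, against 0 genes over all probe sets. The other 11 members included RPA1 at 0.16 and XRCC5 at -0.20, and the list did not pass (median 0.02, 8 of 12 positive, camera adjusted p = 0.619).

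Ribosomal protein transcripts stood higher as a group in anti-DJ1 than in IgG embryos, but did not pass against non-injected embryos (median -0.0097, 26 of 52 positive, camera adjusted p = 0.822). Their median log2 change from IgG embryos was 0.13 (0.10 in trial 1, 0.15 in trial 2), 36 of 52 were positive, 0 passed singly, and the list was the only one of the 20 to pass in limma's camera (adjusted p = 0.0103). The list did not pass with an estimated correlation (p = 0.304, adjusted p = 0.938 with an estimated correlation) or without the block (adjusted p = 0.514). Members ranged from RPL31 at 0.53 ± 0.19 (its second probe set 0.61), RPS21 at 0.50 ± 0.16 and RPS23 at 0.39 ± 0.15 to RPS6 at -0.50 ± 0.18. With 1 array left out and no block, the median was -0.31 without anti-DJ1 replicate 2 (adjusted p = 0.277), -0.24 without IgG replicate 1 (0.687), 0.52 without anti-DJ1 replicate 1 and 0.42 without IgG replicate 2, and the list passed in the last 2. These fits leave the trials unbalanced, and the list is higher in trial 2 by 0.74. The 3′ over 5′ ratio of EF1A was 24.2 in anti-DJ1 against 23.9 in IgG embryos in trial 1, and 8.20 against 9.34 in trial 2. For an actin pair it was 265 against 258, and 45.0 against 68.4. For a GAPDH pair it was 17.6 against 7.46, and 6.65 against 16.1. The 5′ signals of the actin and GAPDH pairs lay near the Tag controls on some arrays. Whether these differences bear on the list was not tested.

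The remaining 18 lists did not pass, with camera adjusted p from 0.103 to 0.981, and 0 of their members passed over all probe sets or adjusted over the list alone. Among lists tied to DJ-1, DJ-1 partners and mitophagy genes had a median log2 change of -0.15 with 2 of 9 positive (adjusted p = 0.3003), with UCHL1, a deubiquitinase, at -0.22 ± 0.10 and the mitophagy kinase PINK1 at -0.23. Oxidative stress genes had a median of -0.02 with 10 of 26 positive (0.495). GPX4, which reduces lipid peroxides, was at -0.55 ± 0.22 (its second probe set -0.53), GCLM at -0.41 and TALDO1 at 0.41. Apoptosis regulators had a median of 0.02 with 7 of 13 positive and the opposite direction in camera (0.908). The death receptor TNFRSF1A was at -0.63 ± 0.20 and BCL2L1 at -0.20, with its second probe set at 0.51.

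Among embryonic functions, cell cycle genes had a median of -0.01 with 8 of 21 positive (camera adjusted p = 0.739), with cyclin A2 (CCNA2) at -0.36. Maternal oocyte transcripts had a median of 0.03 with 6 of 11 positive (0.821), with the egg coat gene ZP2 at 0.19 and BMP15 at -0.15. Genome activation and translation genes had a median of -0.06 with 8 of 25 positive (0.739), with EIF2S1 at -0.30. Pluripotency genes had a median of 0.02 with 6 of 11 positive (0.739), with DPPA5 at 0.26 and POU5F1 at -0.07, and this list passed (adjusted p = 0.0449, median 0.53) when IgG replicate 2 was left out. That fit has no block and sets IgG embryos of trial 1 against anti-DJ1 embryos of both trials, and the list differs by 0.71 between trials. Chromatin genes had a median of -0.06 with 6 of 19 positive (0.598), with the histone methyltransferase EHMT2 at 0.36 ± 0.15 and DNMT1 at -0.20. Imprinted genes had a median of -0.0012 with 6 of 12 positive (0.813), with PHLDA2 at 0.38. Heat shock genes had a median of -0.02 with 7 of 22 positive (0.821), with HSPD1 at 0.22.

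For metabolism and protein turnover, oxidative phosphorylation had a median of 0.06 with 22 of 36 positive (camera adjusted p = 0.371), with ATP5J at 0.45. Proteasome genes had a median of -0.02 with 12 of 28 positive and the opposite direction in camera (0.908), with PSMC6 at 0.89 ± 0.24. Glycolysis had a median of 0.05 with 9 of 16 positive (0.981), with ENO1 at 0.44 and TPI1 at -0.33. Interferon and inflammatory genes had a median of 0.10 with 10 of 15 positive (0.371), with EIF2AK2 at 0.29. For markers of other cells, fibroblast genes had a median of -0.0068 with 10 of 21 positive and the opposite direction in camera (0.371), with COL3A1 at 0.40. Smooth muscle genes had a median of 0.06 with 8 of 13 positive (0.6899), with MYL9 at 0.44. Cumulus and granulosa genes had a median of -0.05 with 4 of 11 positive and the opposite direction in camera (0.819), with INHA at 1.001 ± 0.34 and KRT8 at 0.62 ± 0.23. Epithelial, endothelial and blood markers had a median of 0.24 with 5 of 6 positive (0.103), with CLDN4 at 0.32.

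In trial 1, 997 probe sets differed at least 2-fold between anti-DJ1 and IgG embryos, and in trial 2, 491. In both, 54 changed the same way (28 higher, 26 lower) and 61 in opposite directions. In 15 of the 54, both arrays of the lower group lay under 21.4, the lowest of the 4 arrays' highest Tag signals. The count against each array's own highest Tag signal was not made and can only be as large or larger. Across the 14399 probe sets the log2 ratios of the trials correlated at r = 0.0231 (Spearman rho 0.0276), across probe sets, which are not independent replicates. Transcripts at least 8-fold higher in donor cells than in non-injected embryos (1768 probe sets, median signal 1579.9 against 60.1) shifted by 0.03 between anti-DJ1 and IgG embryos, with -0.02 in trial 1 and 0.08 in trial 2 (SD of members 0.48), and camera called no shift. It called one of 0.10 without IgG replicate 1, in a fit without the block. Transcripts at least 8-fold higher in non-injected embryos (1524 probe sets, median 1248 against 39.1) shifted by -0.0065, with 0.01 and -0.02 (SD of members 0.23), which camera did not call either. The donor-high median of 60.1 in non-injected embryos stands close to that array's highest Tag control of 47.0, which limits what a shift in those transcripts could show.

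**Figure D2:**
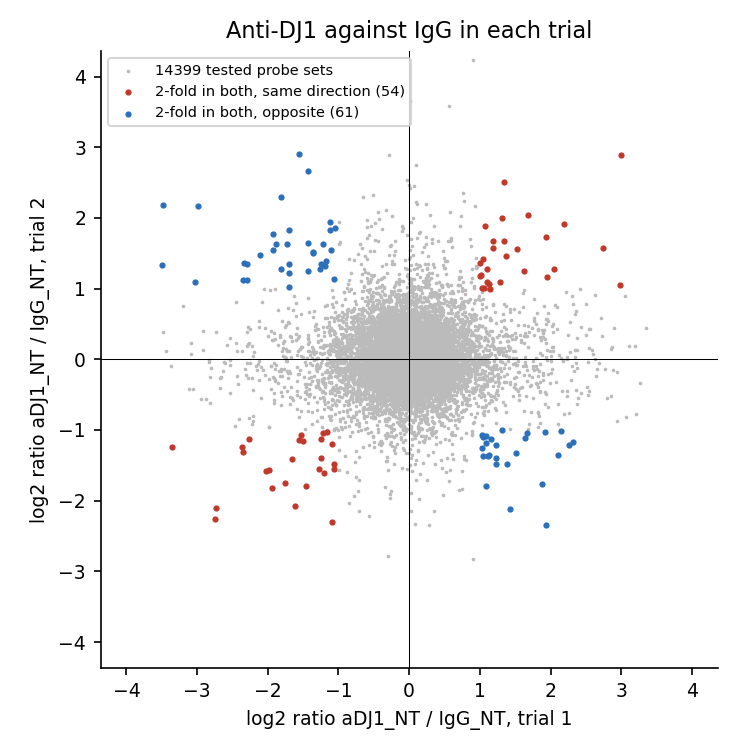
Log2 ratio of anti-DJ1 over IgG embryos in trial 1 (x axis) and trial 2 (y axis) for 14399 probe sets (grey). The 54 probe sets at least 2-fold apart the same way in both trials are red and the 61 in opposite directions are blue, and the ratios correlated at r = 0.0231.

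The comparison of IgG with non-injected embryos addresses the control injection. Of 14399 probe sets, 182 passed (132 higher, 50 lower in IgG embryos), 114 of them at least 2-fold higher and 23 at least 2-fold lower, and 90 genes could be named among them. CCNA2, the cyclin of S phase and mitotic entry, had a signal of 331 ± 8.38 (n = 2) in IgG and 73.1 (n = 1) in non-injected embryos, a log2 change of 1.91 ± 0.36 (limma, adjusted p = 0.0327). The splicing factor SRSF4 rose from 787 to 2731 ± 1.59, by 1.88 ± 0.18 (adjusted p = 0.00114). The chaperone HSPH1 rose from 1489 to 2938 ± 463, by 1.12 ± 0.16 (adjusted p = 0.0077). BSG, a membrane glycoprotein that chaperones lactate transporters, fell by 3.31 ± 0.34 (adjusted p = 0.00122), from 319.6 to 25.4 in trial 1 and 217 in trial 2. Both IgG arrays lay on the same side of the single array for each gene named here as higher or lower.

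Other genes that rose were the thioredoxin-fold protein GLRX3 (1.70 ± 0.24, adjusted p = 0.0077), the X-linked transcription factor ZFX (1.71 ± 0.26, 0.0137, with other probe sets at 0.79 and 2.06), the tight junction gene CLDN12 (1.56 ± 0.26, 0.0212), the proteasome subunit PSMB7 (1.25 ± 0.25, 0.0356) and the translation helicase EIF4A2 (0.79 ± 0.14, 0.0292). Where the non-injected array lay within the Tag controls, the fold is a lower bound on the mean of both trials, with no term for the trial: at least 5.45-fold for YBEY (adjusted p = 0.00114, a second probe set at -0.54), 5.10-fold for the mitochondrial ribosome gene MRPL4 (0.00262), 4.34-fold for the phosphatase gene PHOSPHO1 (0.00122), 3.81-fold for NSFL1C (0.0105) and 2.83-fold for TBRG4 (0.00900). Genes that fell were VPS18 (-1.63 ± 0.35, 0.0492), SCPEP1 (-1.27 ± 0.25, 0.0339), the nucleolar GTPase GTPBP4 (-1.18 ± 0.19, 0.0154), the calpain subunit CAPNS1 (-1.14 ± 0.22, 0.0353, a second probe set at 0.33), the complex I subunit NDUFB1 (-0.95 ± 0.19, 0.0356), the histone methyltransferase EHMT2 (-0.95 ± 0.20, 0.044), the lamina gene LMNB1 (-0.91 ± 0.20, 0.0492), HNRNPA2B1 (-0.90 ± 0.15, 0.0214, other probe sets at 0.15 and 0.34), the redox protein TXN (-0.67 ± 0.14, 0.0483) and beta-actin (ACTB, -0.66 ± 0.13, 0.0404). GNAZ was at least 3.46-fold lower (0.0339). PARK7 was at 0.0097 ± 0.19.

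Under quantile normalization LMNB1, TXN and ACTB no longer passed (adjusted p = 0.0525, 0.0515 and 0.0527), and with no pseudocount EHMT2 and VPS18 did not either (0.0561 and 0.062). With no filter on low values, CCNA2 (0.0801), PSMB7, EIF4A2, HNRNPA2B1, EHMT2, NDUFB1, CAPNS1, SCPEP1, VPS18, GNAZ, LMNB1, TXN and ACTB did not pass. No list passed in camera (adjusted p from 0.420 to 0.870, lowest p with an estimated correlation 0.255). Ribosomal protein genes had a median of -0.15 with 19 of 52 positive, and genome activation genes -0.20 with 8 of 25 positive. Adjusted over the list alone, 3 oxidative stress genes passed (CAT and PRDX1 higher, TXN lower) against 1 over all probe sets. In the same way, 7 genome activation genes passed against 2, 4 maternal genes (BMP15 higher, KPNA7, WEE2 and PTTG1 lower) against 0, 3 heat shock genes against 1, 3 proteasome genes against 1, 2 cell cycle genes (CCNA2 higher, PCNA lower) against 1, 2 chromatin genes against 1, 2 genes of DJ-1 partners (AKT1, PIAS1) against 0, and ACTB in both.

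The EF1A 3′ over 5′ ratio was 30.0 on the non-injected array against 24.2 and 23.9 on the anti-DJ1 and IgG arrays of trial 1, and the median hybridisation control signal was 6155 against 3072 and 2820.1. The comparison rests on that 1 array, and 0 probe sets passed without the block or without the mean-variance trend, with 2493 at an unadjusted p under 0.05 in the fit reported.

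**Figure D3:**
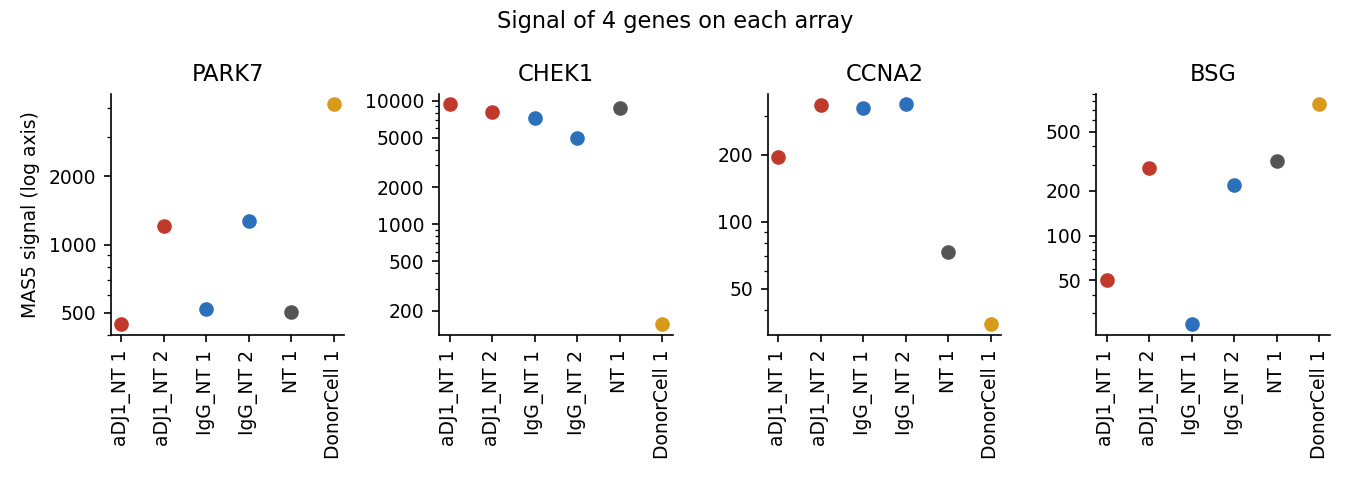
MAS5 signal of PARK7, CHEK1, CCNA2 and BSG on each of the 6 arrays, on log axes. CCNA2 lies at 73.1 in non-injected embryos and at 325 and 337 in IgG embryos, and PARK7 is higher in trial 2 than in trial 1 in both injected groups.

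Anti-DJ1 embryos differed from non-injected embryos at 276 probe sets (182 higher, 94 lower; 147 at least 2-fold higher, 35 at least 2-fold lower), with 125 named genes. ZFX rose by 2.03 ± 0.26 (limma, adjusted p = 0.00518), GLRX3 by 1.59 ± 0.24 (0.0113), EEF1E1, a component of the tRNA synthetase complex, by 1.56 ± 0.30 (0.0282, a second probe set at 0.36), and HSPH1 by 0.97 ± 0.16 (0.0134). MRPL4 was at least 5.10-fold higher (0.00292), YBEY 5.78-fold (0.00102), PHOSPHO1 3.30-fold (0.00292), NSFL1C 3.58-fold (0.0124), ETNK2 3.27-fold (0.0329), RPL29 3.11-fold (0.0404) and TBRG4 2.83-fold (0.00881). These folds average both trials and, unlike the adjusted p, have no term for the trial, so they do not bound the change in the fit. PSMB1 (0.74 ± 0.15, 0.0382) and EIF4A2 (0.65 ± 0.14, 0.0427) also rose. CCNA2 was at 1.54 ± 0.36 and did not pass (0.0519), but passed under quantile normalization (0.0435), a common 75th percentile (0.0327), a pseudocount at the 25th percentile (0.024) and with the upper 40% of probe sets (0.00249).

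Lower in anti-DJ1 than in non-injected embryos were BSG (-2.68 ± 0.34, limma adjusted p = 0.00453), the AMP-activated kinase subunit PRKAA2 (-1.52 ± 0.34, 0.0467), SCPEP1 (-1.50 ± 0.25, 0.0156), the reelin receptor LRP8 (-1.48 ± 0.29, 0.0298), GTPBP4 (-1.21 ± 0.19, 0.012), CAPNS1 (-1.04 ± 0.22, 0.041, a second probe set at 0.39), SH2B1 (-0.99 ± 0.19, 0.0261), MLLT3 (-0.98 ± 0.16, 0.0131), HNRNPA2B1 (-0.79 ± 0.15, 0.0282, other probe sets at 0.47 and 0.23) and TXN (-0.67 ± 0.14, 0.0409). The maintenance DNA methyltransferase DNMT1 fell by 0.75 ± 0.15 (0.0294) and the replication clamp PCNA by 0.62 ± 0.14 (0.046), from 49657.8 to 23841 ± 11114 and from 43696 to 22885.5 ± 9913, and neither call held under quantile normalization, where the changes were -0.11 (adjusted p = 0.675) and 0.0086 (adjusted p = 0.978). With no filter on low values ETNK2, EEF1E1, RPL29, PSMB1, EIF4A2, PCNA, TXN, DNMT1, HNRNPA2B1, CAPNS1, LRP8 and PRKAA2 did not pass, and with no pseudocount EIF4A2, PCNA, TXN, CAPNS1 and PRKAA2 did not. Other DNMT1 probe sets were at -0.21, 0.11 and -1.13. PARK7 was at -0.14 ± 0.19. No list passed (camera adjusted p from 0.388 to 0.925, lowest p with an estimated correlation 0.232). Adjusted over the list alone, 5 heat shock genes (HSPA8, HSPH1, XBP1 and ASNS higher, HSPE1 lower) passed against 1 over all probe sets, 6 genome activation genes against 2, 4 genes of DJ-1 partners (PIAS1 higher, UCHL1, AKT1 and SQSTM1 lower) against 0, 3 maternal genes (KPNA7, WEE2 and PTTG1, all lower) against 0, 3 proteasome genes against 1, 2 cell cycle genes against 1, 2 oxidative stress genes (TXN and MT1A, lower) against 1, 2 smooth muscle genes (MYL9 higher, ACTB lower) against 0, COL3A1 and IFNAR1 against 0 in their lists, and RPL29 and DNMT1 in both.

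The differences from the single non-injected array stand beside its hybridisation control signal of 6155, against 3072 on the anti-DJ1 array of trial 1, and its EF1A ratio of 30.0 against 24.2. Without the block or the mean-variance trend 0 probe sets passed, with 2663 at an unadjusted p under 0.05 in the fit reported, and 1 passed (ACVR1, named after its values were seen, at 4.73 with adjusted p = 0.0413 and 0.0323) when IgG replicate 1 or replicate 2 was left out as well as the block. Whether anti-DJ1 and IgG embryos differ in their distance from non-injected embryos is the comparison of the injected groups given above. Of the 182 probe sets that passed between IgG and non-injected embryos, 133 also passed between anti-DJ1 and non-injected embryos, all in the same direction. The same non-injected array is the reference in both comparisons, so this overlap is not a second observation.

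The embryos were then set against the donor cells whose nuclei they had received. Of 14399 probe sets, 10501 (72.9%) passed, 5248 higher and 5253 lower in embryos, with 4367 at least 2-fold higher and 4530 at least 2-fold lower. The split was 6753 higher and 3923 lower under a common 75th percentile, 6249 and 4227 under quantile normalization, and 5421 and 7293 with no filter on low values. KPNA7, an importin of oocytes, had a signal of 32959 ± 14693.3 (SD, n = 5) in embryos and 5.02 (n = 1) in donor cells, at least 779-fold higher. VIM, the intermediate filament of fibroblasts, had 386 ± 28.1 against 31965.3, a log2 change of -6.34 ± 0.17 (limma, adjusted p = 1.09e-11). PARK7 had 789.9 ± 410.1 against 4153, a change of -3.07 ± 0.17 (adjusted p = 5.24e-09, lower in 5 of 5 embryo arrays, with -3.15 under quantile normalization and -2.44 under a common 75th percentile).

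The median of all 5218 genes was -0.20 as deposited, 0.19 under quantile normalization and 0.43 under a common 75th percentile, so list medians are also given relative to it. All 11 measured maternal oocyte genes rose, with a median of 7.50 (relative 7.70, and 7.48 with quantile normalization; camera adjusted p = 2.54e-07), and the list did not pass with an estimated correlation (p = 0.160, adjusted p = 0.543 with an estimated correlation, as for each list below). The linker histone of oocytes H1FOO was at least 466-fold higher, the egg coat gene ZP4 at least 233-fold and PADI6, a structural protein of the oocyte, at least 128.5-fold, and the meiotic kinase WEE2 rose by 9.07 ± 0.14. Of 21 cell cycle genes 19 rose and 1 fell (median 2.69, relative 2.89; camera adjusted p = 2.31e-06, p = 0.336 with an estimated correlation). Cyclin B1 (CCNB1) rose by 6.84 ± 0.12, PCNA by 6.57 ± 0.12 and the mitotic kinase AURKA by 6.11 ± 0.13.

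Ribosomal protein genes were lower throughout: 52 of 52 fell, with a median of -4.70 (relative -4.51, and -4.96 with quantile normalization; camera adjusted p = 1.27e-15, p = 0.135 with an estimated correlation). RPS26 was at -7.24 ± 0.25, RPS6 at -6.04 ± 0.21, RPL6 at -5.43 ± 0.17 and RPL27 at -4.81 ± 0.16. Of 36 oxidative phosphorylation genes 30 fell and 3 rose (median -2.17, relative -1.97; 3.12e-05, p = 0.120 with an estimated correlation), with the ATP synthase subunit ATP5B at -3.31 ± 0.15 and NDUFB3 at -5.73 ± 0.34. Of 16 glycolysis genes 13 fell and 1 rose (median -2.16, relative -1.97; 0.00376, p = 0.330 with an estimated correlation), with ENO1 at -5.32 ± 0.27 and GAPDH at -4.94 ± 0.15, whose other probe sets were at -4.05, -4.77 and -0.07. Of 26 oxidative stress genes 20 fell and 4 rose (median -2.54, relative -2.35; 0.00551, p = 0.207 with an estimated correlation), with GPX4 at -5.60 ± 0.26, the peroxiredoxin PRDX4 at -4.26 ± 0.17 and ferritin heavy chain FTH1 at -2.37 ± 0.13.

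Of 21 fibroblast and matrix genes 17 fell and 3 rose (median -4.23, relative -4.03; camera adjusted p = 0.0023, p = 0.164 with an estimated correlation). ANXA1 was at -7.26 ± 0.30, fibronectin (FN1) at -5.40 ± 0.17 and SPARC at -4.23 ± 0.14. Of 13 smooth muscle and actin genes 11 fell and 2 rose (median -1.90, relative -1.70; 0.0243, p = 0.222 with an estimated correlation), with CALD1 at -5.53 ± 0.19 and TPM1 at -4.30 ± 0.16. This call ended with only the upper 40% of probe sets (adjusted p = 0.0689) and with the mean of all probe sets of a gene (0.0823). ACTB was at -1.86 ± 0.12, and its second probe set at 1.39. These 8 lists kept their sign under both scalings. The EF1A 3′ over 5′ ratio, 4.23 on the donor cell array and 8.20 to 30.0 on the embryo arrays, differed along with all of them.

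**Figure D4:**
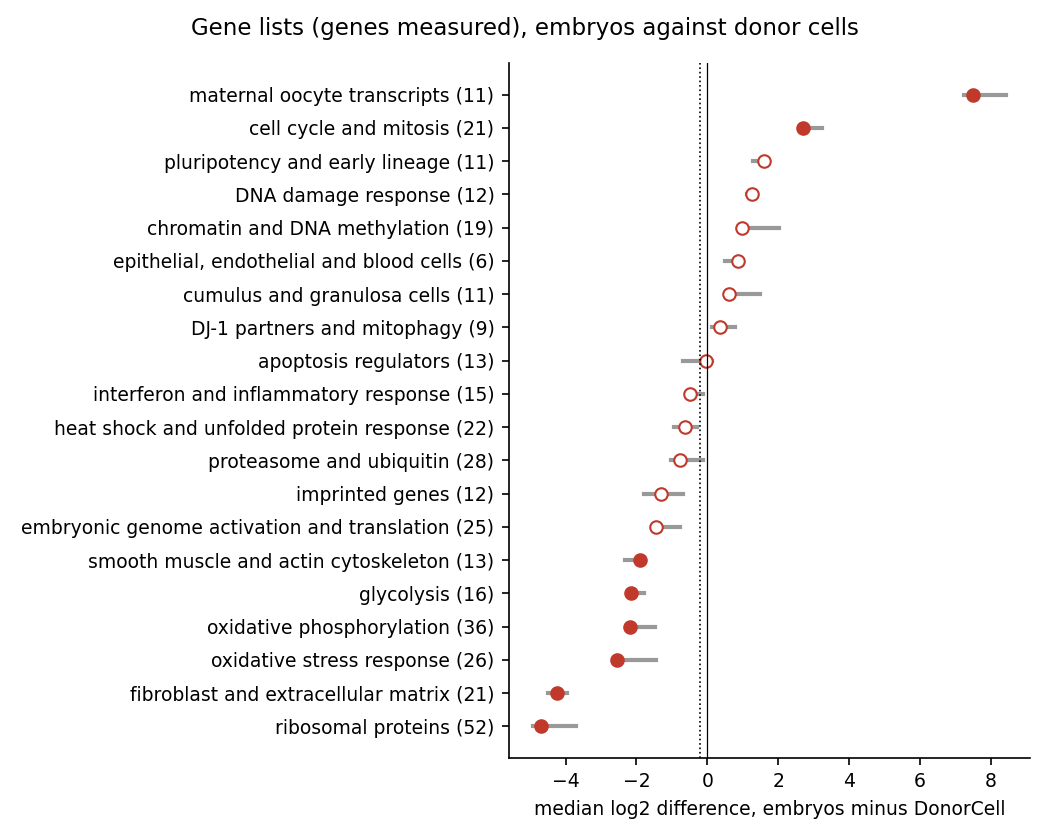
Median log2 difference, embryos minus donor cells, of 20 gene lists (x axis), with the number of genes measured in parentheses. Filled points passed camera (8 lists, with the preset correlation) and open points did not, grey lines run from the lowest to the highest single embryo array's list median, and the dotted line is the median of all genes at -0.20; heat shock and interferon lists turn positive under a common 75th percentile (0.01 and 0.15), and apoptosis regulators do so under both scalings (0.48 and 0.60).

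The other 12 lists did not pass. Of 11 pluripotency genes 7 rose and 3 fell (camera adjusted p = 0.0668), with the pluripotency factor POU5F1 up by 4.14 ± 0.19 and DPPA5 at least 90.9-fold higher. That list passed with only the upper 40% of probe sets (0.00555, median 3.72 against 1.61). Of 19 chromatin genes 12 rose and 4 fell (0.0619), with DNMT1 up by 4.89 ± 0.13, SETDB1 by 3.42 ± 0.12, EZH2 by 3.22 ± 0.15 and the histone chaperone ASF1B at least 44.5-fold higher. That list passed in fits without the block when any 1 of the 4 replicated arrays was left out: 0.0348 without anti-DJ1 replicate 1, 0.0281 without anti-DJ1 replicate 2, 0.0364 without IgG replicate 1 and 0.0259 without IgG replicate 2. Of 12 DNA damage genes 7 rose and 4 fell (0.227), with CHEK1 up by 5.71 ± 0.14. Of 13 apoptosis regulators 6 rose and 5 fell (0.945), with the survival genes BCL2L1 up by 4.32 ± 0.17 and MCL1 at -5.20 ± 0.19. Of 9 DJ-1 partners 4 rose and 3 fell (0.71), with UCHL1 up by 1.23 ± 0.12 and PIAS1 by 2.36 ± 0.13.

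Of 25 genome activation and translation genes 5 rose and 15 fell (camera adjusted p = 0.0917), with SNRPD1 up by 2.54 ± 0.12 and EIF3A at -4.09 ± 0.18. In fits without the block that list passed without anti-DJ1 replicate 1 (0.0486) and without IgG replicate 1 (0.0435). Of 22 heat shock genes 5 rose and 11 fell (0.16), with DNAJA1 up by 1.96 ± 0.11 and HSPA5, the chaperone of the endoplasmic reticulum, at -3.01 ± 0.13. Of 28 proteasome genes 4 rose and 17 fell (0.0619), with UBE2C up by 4.08 ± 0.15 and PSMB7 at -4.47 ± 0.21, and adjusted over the list alone 6 rose and 17 fell. For the other 19 lists the counts adjusted over the list alone equalled those over all probe sets. Of 12 imprinted genes 3 rose and 6 fell (0.487), with PLAGL1 up by 3.30 ± 0.12 and PEG10 at -3.41 ± 0.16. Of 15 interferon and inflammatory genes 3 rose and 8 fell (0.487), with MX1 up by 1.90 ± 0.14 and NFKBIA at -2.21 ± 0.17. B2M, counted among those that rose, was at 0.66, and its other probe sets ran from -6.66 to 1.34. Of 11 cumulus and granulosa genes 5 rose and 1 fell (0.405), with FST at least 9.69-fold higher and KRT8 at -6.86 ± 0.26. Of 6 epithelial, endothelial and blood markers 4 rose and 0 fell (0.102), with TEK at least 38.6-fold higher. Under quantile normalization the heat shock (0.0254), genome activation (0.0227) and proteasome (0.0134) lists also passed, all lower in embryos. The proteasome list passed too with the upper 40% of probe sets (0.042) and with the mean of all probe sets of a gene (0.0362).

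Other named genes that rose were the potassium channel gene KCNN3 (at least 206-fold), FKBP6 (at least 268.5-fold), TMPRSS15 (at least 162-fold), MRAP2 (at least 52.1-fold) and IL12B (at least 49.0-fold). Other named genes that fell were the mechanically induced nuclear protein ANKRD1 (at least 288-fold lower), the transcription factor CEBPD (at least 191-fold lower), PDPN (-8.27 ± 0.25), RGS4 (-8.01 ± 0.32) and the adhesion molecule VCAM1 (-7.98 ± 0.30). The donor cells are a single array, and the count of probe sets past the threshold ranged from 7543 to 12714 over the alternatives.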

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

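The poly-A control transcripts, which are added to RNA before labelling and enter no comparison here, gave a median signal over 21 probe sets of 211 on the anti-DJ1 array and 259 on the IgG array of trial 2, above the highest Tag control of each array. The medians were 3.84, 3.63, 4.82 and 4.48 on the arrays of trial 1. They were listed because a signal appeared in data outside the main measurement, and they split the arrays by trial, not by injection.

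The test of the trial difference by the actin and EF1A controls was chosen after the result was seen, as was the test of correlated variation among ribosomal transcripts; the other tests were written down before their results. Between trials, 4651 probe sets passed within the injected embryos (2728 higher, 1923 lower in trial 2; 1962 and 2187 after quantile normalization, 1662 and 3219 with a common 75th percentile), and this comparison was itself made after the data were seen. A scaling difference does not explain the count, since 4149 passed after quantile normalization. A difference in how much of each transcript was labelled stays open as the source of the count, because the tests cover only a few control transcripts and the GAPDH test cannot decide. The log2 3′ over 5′ ratio was higher in trial 1 by at least 1.36 for the actin and EF1A pairs whose 3′ signal lay away from the Tag controls. Of the 3 GAPDH pairs, the test written first, the one that meets the same rule overlapped between trials (2.90 to 4.13 against 2.73 to 4.01), and the largest gap, 0.39 in the other direction, came from signals near the Tag controls. In the overlapping pair, 5′ signals lay near the Tag controls on arrays of both trials. Those ratios are lower bounds in both trials, including the highest of trial 2 (16.1, IgG embryos). The overlap therefore decides neither for nor against the difference seen in the actin and EF1A pairs. The 5′ signals of the actin and GAPDH pairs lay near the Tag controls on some arrays, and those of EF1A did not. No biological explanation of the trial difference, such as the batch of oocytes, was tested.

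The ribosomal protein list stood higher in anti-DJ1 than in IgG embryos by a median of 0.13. Uniform array scaling alone is unlikely, because it would move random lists too, and 10000 of 10000 random lists had a smaller median shift. Camera had already set the list against other genes on the same arrays, so this adds little to its call. The random lists also lack the correlation between ribosomal protein transcripts. They were matched on mean signal over all arrays, donor cells included. Ribosomal protein transcripts were brighter in donor cells, with a median log2 difference of -4.70 (embryos minus donor cells). The matched lists therefore need not share their signal on the anti-DJ1 and IgG arrays. A bias that follows signal on those arrays stays open, because this test did not match it. Correlated variation of these transcripts between arrays, unrelated to the antibody, stays open. The list shifted by -0.12 between the IgG and non-injected arrays of trial 1, which decides nothing, because that IgG array also enters the anti-DJ1 shift. An effect of blocking DJ-1 on these transcripts also stays open.

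The probe sets that passed between IgG and non-injected embryos could reflect a larger measurement spread of the single non-injected array. Among the brightest 3600 tested probe sets, the spread of non-injected minus IgG was 1.88 times that of anti-DJ1 minus IgG in trial 1 (95% interval 1.76 to 1.98 over 2000 bootstrap draws of probe sets), and 1.16 times among the dimmest. The draws keep the same arrays, so the interval does not cover how far the ratio varies between arrays. A real effect of injection would also widen that spread and stays open. A test of the called probe sets in anti-DJ1 embryos of trial 2 (median 1.27 in the called direction) decides nothing, because the same non-injected array enters both differences.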

How the results depend on the processing

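Each alternative changed 1 choice, except that the fits with an array left out also dropped the block, and the cause of a change was not tested unless stated. Between anti-DJ1 and IgG embryos, 1 probe set passed under quantile normalization, 1 under a common 75th percentile and 1 with the pseudocount at the 25th percentile, the same unnamed one each time (Ssc.7628.1.A1_at), against 0 in the fit reported. In this comparison 0 passed with no pseudocount, no filter on low values, no block for the trial or no mean-variance trend. With the 4 injected arrays only, 2 passed (Ssc.7628.1.A1_at and an unnamed one at -1.78), and with probe sets above the highest Tag control, an alternative chosen after seeing the data, 1 did (Ssc.7628.1.A1_at). With only the upper 40% of probe sets 43 passed (33 higher, 10 lower), in a fit whose prior degrees of freedom of 90.01 leave a gene's own spread almost no weight. Between IgG and non-injected embryos the count of 182 became 348 (75th percentile), 447 (25th percentile pseudocount), 48 (no filter) and 726 (upper 40%), and between anti-DJ1 and non-injected embryos 276 became 502, 589, 71 and 878. Without the mean-variance trend both fell to 0.

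Without the replicate block for the trial, 0 probe sets passed in either comparison with non-injected embryos and 0 lists between anti-DJ1 and IgG embryos. The block changed no other count by over 1.5 times. With an estimated correlation 0 lists passed between anti-DJ1 and IgG embryos and 0 between embryos and donor cells.

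The 54 probe sets changed at least 2-fold the same way in both trials became 20 with the 25th percentile pseudocount (24 opposite), 81 with no pseudocount (74 opposite), 493 with no filter (496 opposite), 5 with the upper 40% (CD151 and unnamed ones at 1.10, 1.10, -1.75 and -1.78; 0 opposite), 307 at a 1.5-fold limit (259 opposite) and 9 at a 3-fold limit (9 opposite). Among probe sets with all 4 arrays above the highest Tag control, chosen after seeing the data, 5 remained, all unnamed (1.10, 1.10, 1.02, -1.35 and -1.78; 3 opposite). Under quantile normalization the shift of embryo-high transcripts was 0.0015 and PCNA in anti-DJ1 against non-injected embryos was 0.0086.

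Leaving out 1 replicate at a time, in fits without the block, which would leave no residual degrees of freedom, and where a lone array is assumed to vary like the replicated groups, gave 0 to 0 probe sets between IgG and non-injected embryos, 0 to 1 between anti-DJ1 and non-injected embryos, and 0 to 2 lists between anti-DJ1 and IgG embryos. These changes cannot be assigned to the array, since the block was dropped too. The ribosomal protein median ran from -0.31 to 0.52, the donor-high shift from -0.056 to 0.096 and the embryo-high shift from -0.0518 to 0.0515. Of the other values under alternatives that kept all replicates, those of named genes kept direction and side of the threshold 677 times between anti-DJ1 and IgG embryos (1 moved, 1 gained the call). The count was 691 between IgG and non-injected embryos (71 lost and 38 gained the call, 14 moved). It was 697 between anti-DJ1 and non-injected embryos (77 lost, 47 gained, 15 moved, 1 opposite) and 783 between embryos and donor cells (7 lost). Values that stayed short of the threshold count as kept. Between anti-DJ1 and IgG embryos no gene passed in the fit reported, so the 677 do not show calls that held. Signal over the Tag controls limits the dim probe sets, where the interval reaches 2.00-fold to either side against 1.21-fold among the brightest.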

Other observations

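Genes in this paragraph were chosen after their values were seen, and none passed in the fit reported. CD151, a tetraspanin of cell adhesion, had signals of 117 and 112 in anti-DJ1 against 37.7 and 34.9 in IgG embryos (limma adjusted p = 0.291, and 0.000559 with only the upper 40% of probe sets). The IgG signal of trial 2 lay within the Tag controls, so no exact fold is given. CD151 was at 97.1 in non-injected embryos and 3289 in donor cells. CXCL14, a chemokine, had signals of 19.4 and 40.8 against 45.8 and 128 at one probe set (adjusted p = 0.816), where the anti-DJ1 signal of trial 1 lay within the Tag controls. At the other, both anti-DJ1 arrays (2.38 and 21.9) lay within the Tag controls, against 42.1 and 122 in IgG embryos.

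The injected embryos differed between trials, a comparison made after the data were seen. PARK7 was 484 ± 53.8 in trial 1 and 1237 ± 48.4 in trial 2 (n = 2 each), a log2 difference of 1.35 ± 0.14 (limma adjusted p = 6.85e-05), larger than its difference between injections. RPL32 was higher by 1.74 ± 0.15, RPS2 by 1.42 ± 0.12 and GAPDH by 1.21 ± 0.13, while ACTB was at -0.90 ± 0.10. A second ACTB probe set went slightly the other way, with 1727 (anti-DJ1) and 2214 (IgG) in trial 1 against 2058 and 2238 in trial 2. ARPC2 had 365 ± 31.0 in trial 1 and 19.3 ± 13.2 in trial 2. Both arrays of trial 2 lay within the Tag controls there, so no exact fold is given. Of 52 ribosomal protein genes 37 were higher and 2 lower in trial 2, with a median of 0.74 (0.49 relative to all genes; camera adjusted p = 6.43e-05, p = 0.234 with an estimated correlation). The other 19 lists did not pass (adjusted p from 0.285 to 0.967).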
